A study of Mus musculus with 6 samples.

How the data were processed

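Transcript levels were measured in mouse multiple myeloma cells, described in the labels as malignant plasma cells from bone marrow, with 1-colour Affymetrix expression arrays. The 6 arrays fell into 2 groups of 3, cells kept in serum-free medium without IGF-1 (control) and cells kept for 12 h in the same medium with 100 ng/ml IGF-1. Per the labels' protocols, total RNA was extracted with TRIzol and cleaned on RNeasy columns, reverse transcribed with oligo-dT primers carrying a T7 promoter, and transcribed into biotinylated cRNA. Priming from the poly(A) tail weights the signal towards the 3′ end of each transcript.

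The deposited values are linear intensities, 1 signal per probe set and array, made by the authors with MAS5 in GCOS, per the submitters' processing notes. The versions of both programs and the scaling target are not given in the sources used here. From the values, the mean signal without the lowest and highest 2% of probe sets was 150.1 in each array, so the arrays had been scaled to 1 common trimmed mean. Such scaling takes the overall RNA output as equal between groups, and every difference is relative to it. MAS5 detection calls were not used here. The medians of the arrays lay between 49.96 and 55.4, the lowest signal was above 0 in all 6, and the number of arrays limits the precision.

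The table held 22690 probe sets. Of these, 64 were control probe sets and were left out of the main test, 20380 carried 1 gene symbol, 691 carried several and 1555 were unlisted in the platform annotation and stay unnamed here. The annotation gave 12393 distinct symbols. Gene identifiers of 20351 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names alone. No gene was named from a probe set with several symbols, and genes whose probe sets were unlisted were not analysed here.

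Signals were tested as log2(signal + 15.57), the pseudocount being the 25th percentile of all signals. No further normalization was applied. Probe sets entered the test when their mean signal over the 6 arrays exceeded 53.61, the median of that mean, which left 11313 probe sets and 6895 genes. IGF-1 arrays were compared with control arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Every adjusted p of a gene is from this limma test. Fold changes are on the log2(signal + pseudocount) scale, which understates changes of dim probe sets. A gene was represented by its brightest tested probe set. Errors of log2 differences are standard errors, and signals are given as mean ± SD of 3 arrays.

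The gene lists and the rule for named genes were fixed before the data were examined, as were the comparison of the groups, the test of the lists and all alternatives except a myeloid marker score as a covariate and scaling to hybridization controls. Further tests chosen later are named as such with their results. There were 23 lists of pathways and complexes and 7 lists of cell type markers. Each list with 5 or more tested members was tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and adjusted over the 25 lists tested. For each list, members past the threshold were counted over all probe sets tested and adjusted over the list alone. The rule named the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap (8 genes with provisional names were passed over), 13 genes fixed for their link to IGF-1, survival or growth, and the leading members of each list. Genes from outside the rule are marked where they appear.

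The fit was tested on 20 simulated data sets of 11313 probe sets, each with 200 changed probe sets. Noise was normal, at limma's moderated spread, which is more even between probe sets than the raw spread of the real arrays. The shares of calls may therefore differ with the real noise. Noise was drawn independently for each probe set, so the simulation cannot check the list test, which depends on the correlation between genes. The shares below hold for 200 changed probe sets, fewer than were called in the real data. At 3 against 3 arrays, 45.4% of the changes of 0.5 and 91% of the changes of 1 (log2) were called, 6.01% of calls were unchanged probe sets, and 0 calls had the wrong sign. Alternatives covered the pseudocount, the filter, the normalization, the eBayes settings, array weights, cross-hybridizing probe sets, the replicate number as a block, each array left out, the correlation used by the list test and the way probe sets were combined. Neither labels nor file named a scan date or a batch. Tables were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and plots were drawn with matplotlib 3.10.9.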

Results

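Gene expression was profiled in mouse multiple myeloma cells, a cancer of antibody-secreting plasma cells, after 12 h in serum-free medium without or with 100 ng/ml insulin-like growth factor 1 (IGF-1), a survival and growth factor for these cells. Each condition was measured on 3 arrays. The comparison asks which transcripts differed in level once IGF-1 was present, among them Bcl2l11, which encodes the pro-apoptotic protein Bim. No label says whether the replicates were separate cultures or animals, so p-values of genes measure the spread between these samples, which may be technical. The list test compares genes with other genes at a preset correlation, so its p-values do not measure that spread. The first principal component held 51.5% of the variance and separated the 3 IGF-1 arrays from the 3 control arrays. Correlations of log2 signals were 0.9777 to 0.9844 within groups and 0.9563 to 0.965 between them. Ratios of 3′ to 5′ signal, a measure of RNA integrity, were 0.748 to 0.843 for Gapdh and 1.163 to 1.311 for actin. They were 2.754 to 3.985 for the transferrin receptor, highest in IGF-1 3, and 1.002 to 4.25 for pyruvate carboxylase, a dim transcript, highest in IGF-1 1. The values of the groups overlapped for all 4.

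Transcripts of cholesterol synthesis showed the largest rises. Msmo1, which encodes a sterol-C4-methyl oxidase, rose 5.69-fold, from a signal of 208 ± 31.3 to 1262 ± 209 (SD, n = 3; log2 difference 2.51 ± 0.14, adjusted p = 7.3e-06). Hmgcs1, the enzyme that makes HMG-CoA at the entry to the pathway, rose 4.11-fold, from 590 ± 98.3 to 2487 ± 481, with 4 of 4 tested probe sets past the threshold. Of the 17 members of the cholesterol synthesis list that were tested, 13 rose, 0 fell and 4 did not pass, and 13 rose adjusted over the list alone. Further examples were Dhcr7 (1.77), Cyp51 (1.77), Idi1 (1.69), Sqle (1.59) and Fdps (1.45), all log2 differences past the threshold. The list median was 1.01 and the list differed from all other genes with an adjusted p of 6.1e-17. It was the 1 list of 25 that also passed with an estimated correlation (adjusted p = 0.018 with an estimated correlation).

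Among transcripts of fatty acid synthesis 5 of 11 tested members rose, 0 fell and 6 did not pass, and 8 rose adjusted over the list alone. The list passed the threshold (median 0.42, adjusted p = 3.1e-06) but not with the other correlation setting (adjusted p = 0.074 with an estimated correlation). Scd2, a desaturase that makes monounsaturated fatty acids, rose from 521 ± 10.7 to 1673 ± 63.6, a log2 difference of 1.65 ± 0.08 (adjusted p = 6.9e-06). Acly, which makes cytosolic acetyl-CoA, rose by 0.77 ± 0.09 and the elongase transcripts Elovl1 and Elovl5 rose by 0.67 and 0.55.

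**Figure D1:**
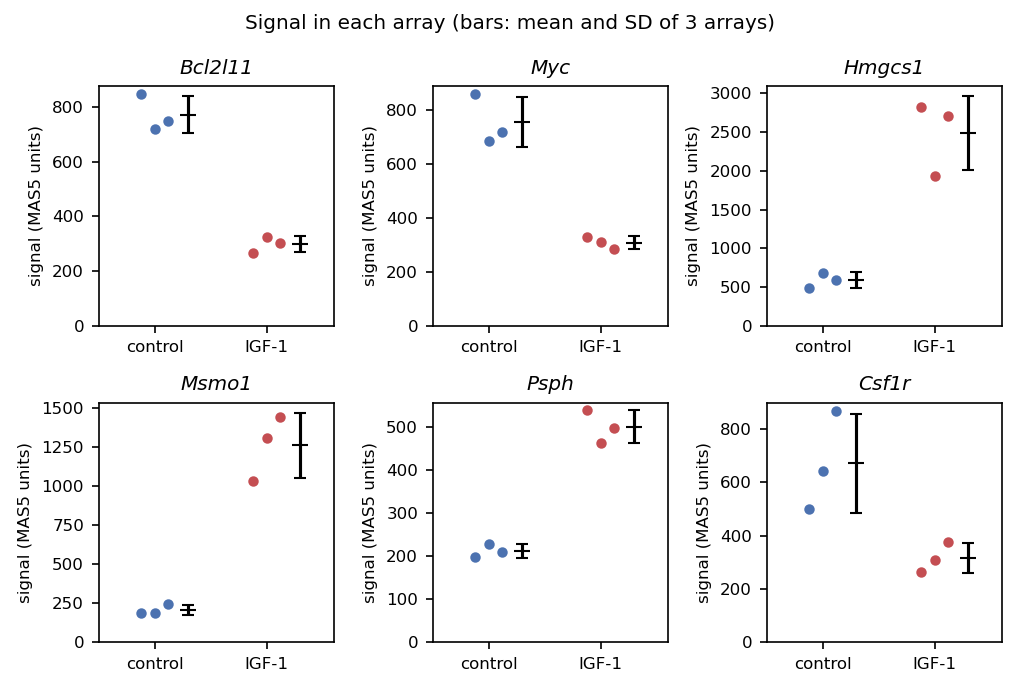
Signal (MAS5 units, linear axis from 0) of 6 transcripts in each of the 3 control arrays (blue) and 3 IGF-1 arrays (red), with black bars for the mean and SD of 3 arrays. Bcl2l11, Myc and Csf1r were lower with IGF-1 and Hmgcs1, Msmo1 and Psph were higher, with no overlap between groups. Bcl2l11 lay between 719 and 848 in controls and between 266 and 325 with IGF-1.

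Bcl2l11 fell with IGF-1. Its brightest probe set went from 772 ± 67.1 to 299 ± 30.1, 2.51-fold lower, with a log2 difference of -1.33 ± 0.11 (adjusted p = 8.1e-05, 3 of 3 IGF-1 arrays below every control array). All 5 tested probe sets of the gene were lower, and 4 passed the threshold with log2 differences from -1.33 to -0.78. The fifth, the dimmest, had a difference of -0.52 ± 0.20 (adjusted p = 0.11). Among 7 tested members of the list of BH3-only and other pro-death BCL2 family genes, 1 fell, 1 rose and 5 did not pass, with the same counts adjusted over the list alone. The member that rose was Bak1, a pore-forming effector of apoptosis, at 0.95 ± 0.15 (adjusted p = 0.0038). The list did not pass (adjusted p = 0.95, median -0.01, mean -0.00028, with the test's direction upward). Its median was 0.27 with scaling to the hybridization controls. Of 3 tested members of the pro-survival BCL2 family, 0 rose and 0 fell, also adjusted over the list alone, too few for a list test. Mcl1 had a difference of -0.20 ± 0.09 (adjusted p = 0.17) and Bcl2l1 one of -0.15 ± 0.11 (adjusted p = 0.43), and both were positive (0.09 and 0.13) when arrays were scaled to the hybridization controls. Bcl2 lay below the signal filter, at 19.9 ± 5.85 and 24.9 ± 6.41.

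Among target genes of FOXO factors, which AKT signalling keeps out of the nucleus, Igf1r, the IGF-1 receptor, fell from 553 ± 42.3 to 364 ± 26.9 (-0.58 ± 0.10, adjusted p = 0.005). Of 20 tested members, 5 fell, 1 rose and 14 did not pass, with the same counts adjusted over the list alone, and 3 fell without control 2, IGF-1 2 or IGF-1 3. Bcl2l11 and Cited2 (-0.46 ± 0.09) were among those that fell, and Tsc22d3, which encodes the glucocorticoid-induced GILZ, rose by 0.49 ± 0.09. The list was lower than other genes (adjusted p = 0.0063, adjusted p = 0.14 with an estimated correlation), and its median of -0.24 became 0.03 when arrays were scaled to the hybridization controls. Foxo1 itself had a difference of -0.47 ± 0.14 (adjusted p = 0.041) that passed in 1 of 3 tested probe sets, and it lost its call without control 1, 2 or 3 or without IGF-1 2 or 3 (highest adjusted p 0.137). Foxo3 did not pass (-0.28 ± 0.15, adjusted p = 0.26, and 0.00 with scaling to the hybridization controls). Of 19 tested components of IGF and insulin signalling, 1 rose, 1 fell and 17 did not pass, unaltered adjusted over the list alone, and 2 fell without control 2 or IGF-1 1. Igf1r fell and Akt1 rose by 0.43 ± 0.10 (adjusted p = 0.018), a call lost without control 3, IGF-1 1 or IGF-1 2 (highest adjusted p 0.0562). The list as a whole did not pass (adjusted p = 0.72, median 0.06, mean -0.06, direction of the test downward), nor did Insr (0.25 ± 0.18, adjusted p = 0.39). Irs1 (32.6 ± 1.67 and 39.9 ± 7.48) and Irs2 (46.1 ± 7.96 and 39.5 ± 14.1) lay below the filter.

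Myc, a transcription factor that drives growth, fell from 753 ± 92.5 to 308 ± 23.3 (log2 difference -1.24 ± 0.11, adjusted p = 0.00014), measured by 1 probe set. Of 16 tested immediate early and ERK-induced genes, 4 fell, 0 rose and 12 did not pass, and 5 fell adjusted over the list alone. Jun fell by 0.47, while Dusp6 (-0.77 ± 0.17) and Spry1 (-0.47 ± 0.12), feedback inhibitors of receptor and ERK signalling, lost their calls with 1 array left out. These were control 2 or 3 for Dusp6 (highest adjusted p 0.0631) and control 1 or 2 or IGF-1 1 or 2 for Spry1 (highest adjusted p 0.0624). The list did not pass (median -0.17, adjusted p = 0.13), but with scaling to the hybridization controls, where its median turned to 0.08, it was lower than other genes (adjusted p = 0.0377). Of 25 tested ribosome biogenesis genes, 0 rose and 0 fell, also adjusted over the list alone (1 rose without control 1 or IGF-1 1), with a median of -0.06 (0.20 under scaling to the hybridization controls) and a list adjusted p of 0.54.

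Genes of the ATF4 amino acid response, which covers serine synthesis, amino acid transport and tRNA charging, were higher as a list (median 0.36, adjusted p = 8.1e-12), but not with the other correlation setting (adjusted p = 0.14 with an estimated correlation). Of 29 tested members, 15 rose, 0 fell and 14 did not pass, and 18 rose adjusted over the list alone. With 1 array left out, 10 to 17 rose. Psph, the last enzyme of serine synthesis, rose from 212 ± 15.6 to 499 ± 38.4 (1.18 ± 0.10, adjusted p = 0.00012). Stc2 rose by 0.93 ± 0.10, the seryl-tRNA synthetase transcript Sars by 0.72 ± 0.08, and Phgdh, which starts serine synthesis, by 0.59 ± 0.10. Cth, an enzyme of cysteine synthesis named for its size of change, rose from 80.8 ± 17.8 to 314 ± 30.8. Of 26 tested endoplasmic reticulum chaperones and unfolded protein response genes, 8 rose, 0 fell and 18 did not pass, and 10 rose and 1 fell adjusted over the list alone. Of these calls, 3 rises were left without IGF-1 1 or IGF-1 2, 4 without control 2 and 5 without control 3 or IGF-1 3. Sdf2l1 rose by 0.75 ± 0.11, Pdia4, a disulfide isomerase, by 0.73 ± 0.14 and Derl1 by 0.46 ± 0.08. By sign alone, 20 of the 26 were higher and 6 lower. Outside the rule and picked after their values were seen, Hspa5 (0.07) and Xbp1 (-0.19) did not pass. Dnajb9, picked likewise, was the 1 that fell adjusted over the list alone (-0.43). The list median was 0.17 (adjusted p = 0.0017, adjusted p = 0.14 with an estimated correlation).

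**Figure D2:**
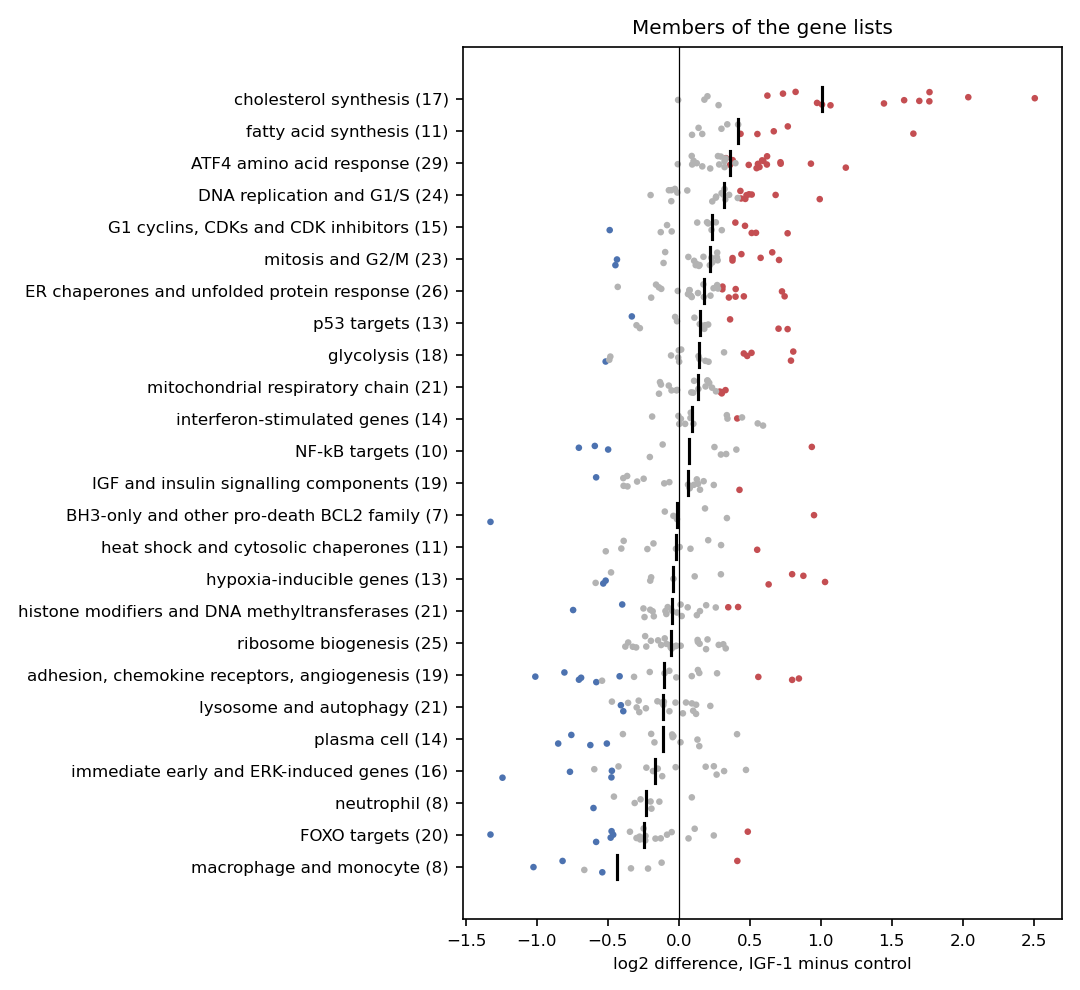
Log2 difference (IGF-1 minus control, horizontal axis) of every tested member of the 25 lists with a list test, 1 dot per gene, with the number tested in brackets and the list median as a black bar. Red dots rose, blue dots fell and grey dots did not pass the threshold. Cholesterol synthesis had the highest median, 1.01, and the macrophage and monocyte list the lowest, -0.44, in the authors' scaling.

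Genes of DNA replication and of mitosis were higher as lists (adjusted p = 6.9e-05 and 0.0032), but not with the other correlation setting (adjusted p = 0.22 and 0.46 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, rose from 76.4 ± 13.2 to 167 ± 21.6 (0.99 ± 0.15, adjusted p = 0.0024) and Pcna, the replication clamp, rose by 0.44 ± 0.08. Of 24 tested DNA replication and G1/S genes, 8 rose, 0 fell and 16 did not pass, and 13 rose adjusted over the list alone (median 0.32). With 1 array left out, 3 rose without IGF-1 1, 4 without control 2 and 5 without control 3 or IGF-1 2. Plk1 and Ccna2, regulators of mitosis and of S and G2 phases, rose by 0.71 ± 0.10 and 0.58 ± 0.10. Of 23 tested mitosis and G2/M genes, 6 rose, 2 fell and 15 did not pass, and 8 rose and 2 fell adjusted over the list alone (median 0.22), and 3 rose without control 2, IGF-1 1 or IGF-1 2. The mitosis list's call was also lost with the myeloid marker score in the model. Those that fell were Cenpa and Kif11 (-0.44 and -0.45), with calls lost without control 1, control 2 or IGF-1 3, and for Kif11 also without IGF-1 2 (highest adjusted p 0.0819 and 0.0919).

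Among G1 cyclins, CDKs and CDK inhibitors, both drivers and brakes of the cell cycle rose. Cdkn1a, which encodes the inhibitor p21, rose from 746.5 ± 48.5 to 1279.7 ± 48.7 (0.77 ± 0.09, adjusted p = 0.00067), and the D-type cyclin transcripts Ccnd3 and Ccnd2 rose by 0.51 ± 0.10 and 0.54 ± 0.10. Ccnd2 passed in 1 of 5 tested probe sets, and Ccnd1 did not pass (0.20 ± 0.16, adjusted p = 0.44). Of 15 tested members, 5 rose, 1 fell and 9 did not pass, and 7 rose and 1 fell adjusted over the list alone (median 0.23, list adjusted p = 0.0052, adjusted p = 0.22 with an estimated correlation). The other 2 that rose were the inhibitor transcripts Cdkn2a and Cdkn2b (0.47 and 0.40), whose calls were lost without control 2 or 3 or IGF-1 2 or 3, and for Cdkn2b without control 1 (highest adjusted p 0.0909 and 0.148). Rb1, a brake on S phase entry, fell by 0.49, a call lost without control 2, IGF-1 2 or IGF-1 3 (highest adjusted p 0.0575). Of 13 tested p53 target genes, 3 rose, among them Cdkn1a and Gtse1 (0.70 ± 0.12), 1 fell (a call lost without any array but control 1) and 9 did not pass, with the same counts adjusted over the list alone, a median of 0.15 and a list adjusted p of 0.19. The remaining rise was lost without each of the 6 arrays in turn (highest adjusted p 0.133).

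In glycolysis, Slc2a1, the glucose transporter GLUT1, rose from 565 ± 62.0 to 998.5 ± 72.4 (0.81 ± 0.10, adjusted p = 0.0012), Aldoc by 0.79 ± 0.09 and Pkm by 0.51 ± 0.10. Of 18 tested members, 5 rose, 1 fell and 12 did not pass, and 6 rose and 2 fell adjusted over the list alone (median 0.14). There were 3 that fell without control 1 and 0 without control 2, control 3 or IGF-1 2. The list passed with an adjusted p of 0.036 (adjusted p = 0.62 with an estimated correlation), but not without control 1 (adjusted p = 0.217) or without IGF-1 3 (adjusted p = 0.124), nor with quantile normalization. Of 13 tested hypoxia-inducible genes, 4 rose, 2 fell and 7 did not pass, and 5 rose and 3 fell adjusted over the list alone, and 1 fell without control 2, control 3 or IGF-1 2. Ero1a, an oxidase of the endoplasmic reticulum, rose 2.04-fold, from 1261 ± 176 to 2577 ± 94.9, Vegfa by 0.80 ± 0.12 and P4ha1 by 0.63 ± 0.11, while Mxi1 fell by 0.53. That list did not pass (adjusted p = 0.54) and its median (-0.04, but 0.25 with scaling to the hybridization controls) had the opposite sign to its mean (0.09), and it passed with the myeloid marker score in the model (median 0.13, adjusted p = 0.02057). Of 21 tested genes of the mitochondrial respiratory chain, 4 rose, 0 fell and 17 did not pass, with the same counts adjusted over the list alone. Only 1 rose without control 1 or control 2, and 0 rose without control 3 or any 1 IGF-1 array. Its median was 0.14, and Sdhb had the smallest p (0.33 ± 0.09, adjusted p = 0.029, lost without control 3 or any 1 IGF-1 array, highest adjusted p 0.0886). The list passed with an adjusted p of 0.03 (adjusted p = 0.3 with an estimated correlation), but not without control 3 (adjusted p = 0.0985), IGF-1 1 (adjusted p = 0.0636) or IGF-1 3 (adjusted p = 0.0556), nor with quantile normalization, a filter at the 70th percentile, the mean of probe sets per gene or the myeloid marker score in the model.

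Transcripts known from neutrophils and macrophages gave signal in these samples. Mean signals of 8 neutrophil markers over the 6 arrays lay between 238 for Prtn3 and 6872 for S100a9, the latter chosen for its signal after its values were seen. Signals of different probe sets do not compare transcript levels. Of 8 tested neutrophil markers, 1 fell, 0 rose and 7 did not pass, also adjusted over the list alone. The 1 was Ltf (-0.60 ± 0.13, adjusted p = 0.012, and 0.0522 without IGF-1 2), and 2 fell without IGF-1 3. The neutrophil list was lower than other genes (median -0.23, adjusted p = 0.025, adjusted p = 0.56 with an estimated correlation), a call lost without control 3 (adjusted p = 0.0944), IGF-1 1 (adjusted p = 0.0966) or IGF-1 2 (adjusted p = 0.062), and its median became 0.05 with scaling to the hybridization controls. That scaling also ended its call. Of 8 tested macrophage and monocyte markers, 3 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone, and 1 fell without control 2, control 3, IGF-1 1 or IGF-1 2. Csf1r, the receptor for macrophage colony-stimulating factor, fell from 671 ± 185 to 317 ± 55.6 (-1.02 ± 0.18, adjusted p = 0.0059). Cd68, a lysosomal glycoprotein, rose by 0.41 ± 0.09 (adjusted p = 0.012, and 0.0519 without IGF-1 2). The list median was -0.44, with an adjusted p of 0.075, which fell below the threshold without control 1 or without IGF-1 3 (adjusted p = 0.008308 and 0.006515). It also passed without a filter (adjusted p = 0.01881) and with the replicate number as a block (adjusted p = 0.00907). Scaling to the hybridization controls gave a pass too (median -0.16, adjusted p = 0.005029).

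Of 19 tested genes of adhesion, chemokine receptors and angiogenesis in myeloma, 3 rose, 6 fell and 10 did not pass, and 3 rose and 7 fell adjusted over the list alone. Of the falls, 3 were left without control 2, and 2 without control 3, IGF-1 1 or IGF-1 2. Cxcr4, the CXCL12 receptor that holds cells in marrow, fell from 795.5 ± 165 to 442 ± 32.8 (-0.81 ± 0.14, adjusted p = 0.0056), and Il6st, the signalling subunit of the interleukin-6 receptor, fell by 0.69. Itgal, an integrin subunit, rose by 0.56 ± 0.09. The list did not pass (adjusted p = 0.4, median -0.10, but 0.13 with scaling to the hybridization controls). Of 14 tested plasma cell markers, 4 fell, 0 rose and 10 did not pass, and 5 fell and 1 rose adjusted over the list alone. Pim2, a survival kinase, fell from 245 ± 36.7 to 128 ± 13.0 (-0.85 ± 0.13, adjusted p = 0.0028) and Tnfrsf17, the receptor BCMA, by 0.51. Jchain (-0.04) and Sdc1 (0.14), which mark plasma cells and were chosen after their values were seen, did not pass. The list did not pass (adjusted p = 0.072, median -0.11, but 0.17 with scaling to the hybridization controls), and it passed without control 2 (adjusted p = 0.03064) or control 3 (adjusted p = 0.02402). It also passed with quantile normalization (adjusted p = 0.01879), without a filter (adjusted p = 0.03247), with the mean over probe sets (adjusted p = 0.0299) and with the myeloid marker score in the model (median -0.29, adjusted p = 0.002937). Of 3 tested B cell markers, 1 fell (H2-Aa, -0.64 ± 0.10), 1 rose (Cd74, 0.32 ± 0.08, lost without any array but control 2, highest adjusted p 0.0983) and 1 did not pass, with the same counts adjusted over the list alone. Of 2 erythroid markers 1 rose (Slc4a1, 0.54 ± 0.12, adjusted p = 0.017, and at most 0.0566 without control 2, IGF-1 1 or IGF-1 2), and of 2 stromal and endothelial markers 0 passed, both also adjusted over the list alone. T cell markers had 0 members above the filter.

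The remaining lists did not pass with the settings described. Of 10 tested NF-kB targets, 1 rose, 3 fell and 6 did not pass, and 2 rose and 3 fell adjusted over the list alone (list adjusted p = 0.95, median 0.07). Of the falls, 0 were left without control 2, control 3, IGF-1 1 or IGF-1 2, and 1 without IGF-1 3. Icam1 had a difference of 0.94 ± 0.23 and lost its call without control 2, IGF-1 2 or IGF-1 3 (highest adjusted p 0.0841). Of 14 interferon-stimulated genes, 1 rose (Psmb9, 0.41 ± 0.10, lost without control 1, control 2, IGF-1 1 or IGF-1 3, highest adjusted p 0.0851), 0 fell and 13 did not pass, also adjusted over the list alone. That list had a median of 0.09 and an adjusted p of 0.054 (adjusted p = 0.73 with an estimated correlation). It passed without control 3 (median 0.36, adjusted p = 0.002204, 3 rose) or IGF-1 1 (median 0.34, adjusted p = 0.003549), with array weights (median 0.15, adjusted p = 0.02852) and with the myeloid marker score in the model (median 0.70, adjusted p = 2.694e-09). With the replicate number as a block it passed as well (median 0.09, adjusted p = 0.01855). Of 21 lysosome and autophagy genes, 2 fell, 0 rose and 19 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.12, or 0.04431 without a filter, median -0.11, but 0.17 with scaling to the hybridization controls). They were Map1lc3b (-0.39 ± 0.09, lost without IGF-1 1 or IGF-1 3, highest adjusted p 0.0595) and Ulk1 (-0.41 ± 0.11, lost without any array but IGF-1 2, highest adjusted p 0.107). Of 21 histone modifiers and DNA methyltransferases, 2 rose, 2 fell and 17 did not pass, also adjusted over the list alone. Of the rises, 0 were left without control 2, control 3, IGF-1 2 or IGF-1 3 and 1 without control 1 or IGF-1 1, and of the falls 1 without control 2, IGF-1 1 or IGF-1 3. That list did not pass (list adjusted p = 0.88, median -0.05, but 0.22 with scaling to the hybridization controls), and the deacetylase transcript Sirt1 fell from 215 ± 35.3 to 121 ± 16.5. Of 11 cytosolic chaperones, 1 rose (Stip1, 0.55 ± 0.10) and 10 did not pass, though 2 fell without control 1 and 1 without IGF-1 1, and 1 rose and 2 fell adjusted over the list alone (list adjusted p = 0.79, median -0.02, but 0.27 with scaling to the hybridization controls).

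Outside the lists, the largest falls were those of Zfp932, a zinc finger gene (277 ± 17.7 to 50.5 ± 17.6, log2 difference -2.18 ± 0.17, adjusted p = 7.8e-05), and Mogat2, an acyltransferase of triglyceride synthesis (-2.08 ± 0.18). They were followed by Abca3, Trdn, Il16, Tor4a, Pla2g7, Tmem71, Ypel3, Themis2 and Pcmtd2, with log2 differences from -1.70 to -1.32. Ypel3 was the brightest of them, at 1174 ± 152 and 448 ± 14.3. Reep6 (1.84 ± 0.15) and Bhlhe41, a transcriptional repressor (1.49 ± 0.10), completed the largest rises.

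In all, 772 probe sets were higher and 937 lower with IGF-1, or 486 and 555 genes, with 4 genes called in both directions by different probe sets and 137 called probe sets without a single gene name. Of all called probe sets, 43 were higher and 60 lower by 2-fold or more. At an unadjusted p under 0.05 there were 3445 probe sets, and in 3940 (34.8%) the groups did not overlap, against 10% by chance for 3 against 3. Calls came to 946 without control 2, 1126 without control 3, 901 without IGF-1 2 and 1059 without IGF-1 3, against 1709 with all arrays. Of the 126 named genes past the threshold, 73 kept their call without each array in turn. The higher share of the calls was 45.2%, but 55.3% after median centring (948 higher, 766 lower) and 91.8% after scaling to the hybridization controls (2749 higher, 246 lower), which raised the median difference of all probe sets from -0.01 to 0.25. With a score of the myeloid markers in the model, 651 probe sets passed, and 65 named genes lost their calls. Of these, 4 are part of the score, so that their losses carry no information, and the others described were Pla2g7, Ccnd2, Ccnd3, Bak1, Tsc22d3, Cited2, Jun, Elovl5, Mxi1, Pdia4, Gtse1, Cxcr4, Sirt1, Tnfrsf17, Foxo1, Akt1, Dusp6, Spry1, Cdkn2a, Cdkn2b, Map1lc3b, Ulk1, Icam1, Sdhb, Cd74 and Slc4a1. The score also widened standard errors, from 0.108 to 0.149 for Bcl2l11 and from 0.111 to 0.128 for Myc, whose differences did not shrink. A call lost with the score thus does not by itself tie a gene to myeloid cells. Scaling to the hybridization controls ended 27 calls of named genes, among those described Igf1r, Cited2, Jun, Mxi1, Tnfrsf17, H2-Aa, Foxo1, Spry1, Cenpa, Kif11, Rb1, Map1lc3b, Ulk1, Cd14 and Ltf. The mean over probe sets ended 15 calls of named genes, among those described Ccnd2, Jun, Vegfa, Derl1, Csf1r, Foxo1 and Ulk1. The test without a filter ended 44, among those described Pla2g7, Foxo1, Dusp6, Spry1, Kif11, Cdkn2a, Cdkn2b, Ulk1, Psmb9, Icam1, Sdhb, Cd74 and Cd14. Quantile normalization ended 12, among those described Foxo1, Cdkn2b, Ulk1 and Cd14. Median centring ended 6, among those described Foxo1, Ulk1 and Cd14. Without a trend, eBayes ended 19, among those described Foxo1, Cdkn2b, Sdhb, Cd74 and Cd14.

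**Figure D3:**
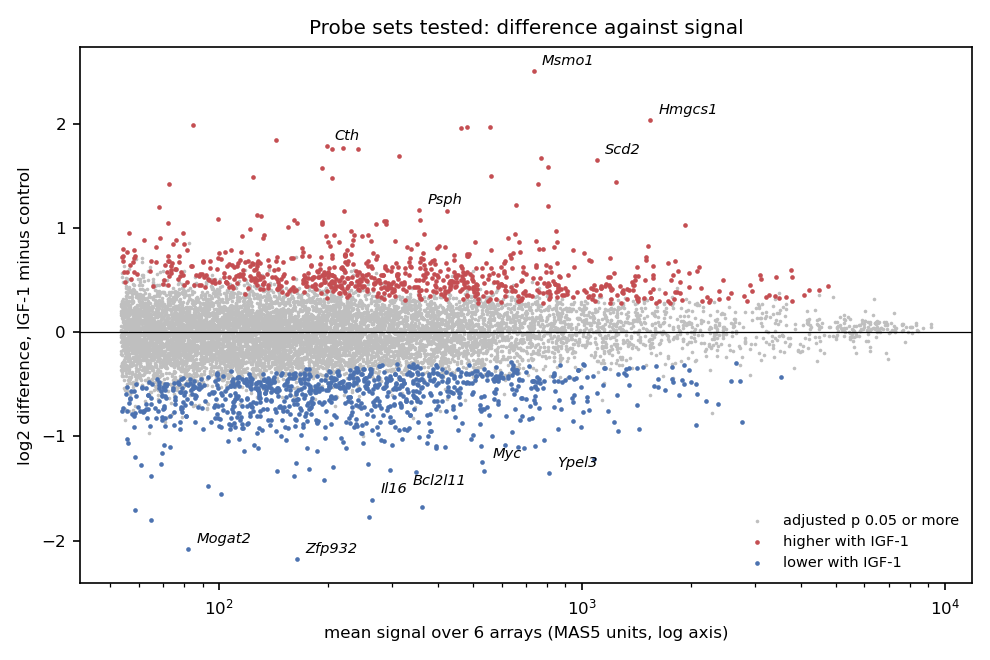
Log2 difference (IGF-1 minus control, vertical axis) against mean signal over 6 arrays (MAS5 units, log axis) for the 11313 tested probe sets. Red marks the 772 probe sets higher and blue the 937 lower with IGF-1, grey the others, and names mark 11 of the named genes at their brightest probe set.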

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

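The tests on scaling, on macrophage markers and on neutrophil markers were chosen after the results were seen. The tests with the myeloid score were written down before their results, with a score that was itself added after seeing the data.

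Some control probe sets outside the main test differed between groups. Over the 64 control probe sets, limma put 3 past the threshold. The spiked bioD control was lower with IGF-1 in 2 probe sets, at -0.431 (642 ± 31.6 to 472 ± 27.6, adjusted p = 0.019) and -0.400 (690 ± 23.4 to 519 ± 28.0, adjusted p = 0.019). Its other probe sets did not pass, at -0.407 (adjusted p = 0.053) and -0.048 (adjusted p = 0.95). A probe set for the 5′ part of 18S ribosomal RNA was higher by 0.748 (adjusted p = 0.035), at signals of 4.88 ± 4.06 and 18.4 ± 2.39, close to the floor.

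More probe sets were lower than higher, 937 against 772. All 18 hybridization control probe sets, for transcripts added to each sample before hybridization, were lower with IGF-1 (median -0.283, from -0.431 to -0.0135). They cover only bioB, bioC, bioD and cre and share each array's scaling, so they are not 18 independent measurements. Scaled to them, 91.8% of the calls were higher, so the balance of directions may be set by the scaling to 1 trimmed mean. Transcripts added at that step do not measure the cells' RNA output. Whether the spiked amounts differed between samples was not tested.

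Of 8 macrophage and monocyte markers, 3 fell, 1 rose and 4 did not pass, and the list did not pass (median -0.44, adjusted p = 0.075, adjusted p = 0.68 with an estimated correlation). A smaller share of such cells would lower them all by about the same amount. Each marker set against the mean of the other markers showed Cd68 higher by 0.94 ± 0.20 (limma, adjusted p = 0.00396), Csf1r lower, at -0.70 ± 0.10 (adjusted p = 0.000667), and Cd14 lower, at -0.46 ± 0.16 (adjusted p = 0.0476). These differences were visible before the test, Csf1r and Cd14 are the markers that fell most, and Cd68 is 1 gene that other cells may express, with a call lost without IGF-1 2. Without Cd68 the other 7 were still lower by unequal amounts, led by Csf1r, with 3 of them past the threshold. This rests on the approximate Cochran's Q (19.1 against a chi-square 95% point of 12.6). Signal from other cells or near background may also make falls unequal, so fewer macrophages cannot be told apart from an effect within the cells. Among 8 neutrophil markers the smallest such adjusted p was 0.0614, and 5 lie above the 98th percentile of signal, where changes may be compressed, so fewer neutrophils cannot be told apart from an effect within the cells. The choice of test matters here: Cochran's Q, run first and replaced because approximate p-values are not used here for so few values, was 84.2 for macrophage and 15.6 for neutrophil markers, both above the chi-square 95% point of 14.1. By that first test both explanations would have been counted out. The exception for bright markers and the need for more than 1 rising macrophage marker were added only after the results had been seen.

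Myc and Bcl2l11 were lower with IGF-1, in samples that also gave signal for transcripts known from myeloid cells. With the myeloid score in the model, the difference of Myc was -1.43 ± 0.13 (adjusted p = 0.00036) and that of Bcl2l11 -1.36 ± 0.15 (adjusted p = 0.00122), against -1.24 and -1.33 without it. Over the alternatives their highest adjusted p were 0.001835 and 0.001373. Both would have shrunk if a smaller share of myeloid cells alone lay behind them and the score tracked that share. Neither shrank, but the score's macrophage markers moved unequally. The score also rose with replicate number in both groups (control -0.09, 0.21 and 0.39, IGF-1 -0.34, -0.24 and 0.07). It may therefore not measure that share, and the test does not settle the question. A direct effect of IGF-1 on these transcripts stays an untested hypothesis.

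There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 1709 calls, a count reached by 1 of the 10, and the highest other split gave 0. For gene lists, 2 of the 10 gave as many as the real 11, the highest other being 13, from control 1, IGF-1 1 and IGF-1 2 against the rest. Every other split put at least 2 lists past the threshold, though each had 0 called probe sets. The list test at the preset correlation thus also passed lists in mixed groupings.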

How the results depend on the processing

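The myeloid marker score and the scaling to the hybridization controls were chosen after seeing the data, the other alternatives before.

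The Bcl2l11 difference stayed past the threshold under all 20 alternatives run for it, from -1.389 to -0.9224. Cholesterol synthesis passed under all 21 of its alternatives. Without a filter, 448 probe sets were higher and 498 lower (946 in all, over 22626 tested), a larger number over which p-values are adjusted. With the myeloid score, 287 were higher and 364 lower (651 in all, of which 557 were shared with the reported calls), and the cause was not tested. Scaling to the hybridization controls gave 2749 higher and 246 lower (2995 in all, 1018 shared), since it moves each array's level. Leaving out 1 array at a time gave 404 to 663 higher, 497 to 785 lower and 901 to 1448 in all, with fewer samples, and 10 to 12 gene lists. With an estimated correlation 1 gene list passed in place of 11. For FOXO targets and fatty acid synthesis the estimate (-0.033 and -0.0011) lay below the preset 0.01. A higher correlation therefore does not account for these losses. In the other lists that lost their call the estimate lay above 0.01, and the cause was not tested. Other alternatives gave 1392 to 1848 calls. Of 155 named genes tested, 126 were past the threshold. Of these 126, 44 lost their call without a filter, 65 with the myeloid score (4 of them part of it) and 27 with scaling to the hybridization controls. With 1 array left out, 21 to 43 lost it, and 49 of the 126 kept it under every alternative that tested them. Medians of FOXO targets (0.03) and neutrophil markers (0.05) turned positive under scaling to the hybridization controls, since that scaling raises all differences. The list test, which is relative to other genes, kept its downward direction, with an adjusted p of 0.00715 for FOXO targets and 0.112 for neutrophil markers.

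With the replicate number as a replicate block, 754 probe sets were higher and 978 lower (1732 in all, 1523 shared) and 13 lists passed, with those of interferon-stimulated genes (adjusted p = 0.01855) and of macrophages and monocytes (adjusted p = 0.00907) added, while 10 named genes, Cdkn2b among them, lost their calls. Deviations of same-numbered arrays correlated at 0.12, -0.0334 and 0.127, and those of differently numbered arrays at -0.149 to 0.029. The second principal component (15.5% of the variance) ordered the arrays by number in both groups. Its scores were 12.26, -0.7541 and -9.605 for controls 1 to 3 and 13.28, -6.046 and -9.129 for IGF-1 1 to 3. A structure shared by number is thus left open. The labels do not say that the numbers pair the samples, so the reported fit has no block. Dim probe sets limit the data, since genes under the filter were not tested in the reported fit.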

Other observations

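The grouping by symbol and the look below the filter were chosen after the results were seen, as was the ribosome biogenesis test.

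Genes were also grouped by the first letters of their symbols, 58 groups with 15 or more tested genes, of which 4 passed with limma's camera. Proteasome genes (Psm, 47 genes) had 7 that rose and 0 that fell (median 0.12, adjusted p = 0.0096, and a median of 0.4 with scaling to the hybridization controls). Genes of respiratory complex I and its assembly (Ndu, 38 genes) had 4 that rose and 0 that fell (median 0.14, adjusted p = 0.023). Their median was 0.42 with that scaling, and some of them are in the respiratory chain list. Zinc finger genes (Zfp, 77 genes) had 10 that fell and 0 that rose (median -0.15, adjusted p = 0.025, but a median of 0.12 with scaling to the hybridization controls). Symbols starting Il1, a mix of interleukins and receptors, had 4 of 17 that fell (median -0.26, adjusted p = 0.031, but a median of 0.01 with that scaling). None of the 4 passed with an estimated correlation (adjusted p = 0.69 with an estimated correlation for each).

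Below the signal filter, Fbxo32, a ubiquitin ligase gene and FOXO target, was lower with IGF-1, at signals of 80.1 ± 3.62 and 15.5 ± 5.70 (adjusted p = 0.0046 without a filter). Adm, which encodes the peptide adrenomedullin, went from 29.1 ± 4.47 to 64.4 ± 6.38 (0.84 ± 0.16, adjusted p = 0.030 without a filter). Crebbp, which encodes a histone acetyltransferase, was lower, at 24.8 ± 6.37 and 7.07 ± 3.13 (adjusted p = 0.039 without a filter). The lower means of Fbxo32 and Crebbp lie below the 25th percentile of all signals, 15.57, so no size of change is given for them. These were the 3 past the threshold among 112 list members below the filter, and they were picked after their values were seen.

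One hypothesis was that the lower Myc transcript level was followed by lower transcripts of ribosome biogenesis, a set that MYC is known to activate. Its prediction was a list median at or below -0.3, a bound set when the median was already known. The median over 25 genes was -0.0579, with 9 genes above 0, 16 below 0 and an SD of 0.211 across genes, and 0 genes passed. That median did not meet the prediction. Since the bound was set late and members went both ways, a smaller effect is left undecided, and MYC protein was not analysed here.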
